A study of Drosophila melanogaster with 2 samples.

How the data were processed

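Total RNA from hindguts of young and mature adults was extracted with Trizol and sequenced in read pairs on a NovaSeq instrument, per the labels' protocols. Trim Galore, HISAT2, DESeq2 and the genome build BDGP6 are named, without versions, in the submitters' processing notes. The program that counted reads per feature, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes may not have been told apart. The labels give 2 samples, 1 per age, each covering 3 replicates; nothing says how the replicates were formed, and the p-values measure only the spread between these libraries, which may be technical.

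The authors' deposited table has 1 row per feature. Its mean column is a signal that is never negative, which DESeq2 defines as the mean of normalized counts over the libraries, per the file headers. The fold change, given as young against mature, and its standard error were read as log2 values, the base that DESeq2 reports, per the file headers and the names of the 2 deposited lists, which set the direction. The Wald score deposited by the authors equals the fold change divided by its standard error. The p-value and the adjusted p-value deposited by the authors are those of the DESeq2 Wald test; recomputing the Benjamini-Hochberg adjustment over the 10458 features with an adjusted value gave the same numbers. Of 23932 features, 8929 had a mean of 0, 14966 had a p, 37 had a fold change without a p and 4508 had a p without an adjusted p; the lowest mean with an adjusted p was 6.11. The standard error had a ceiling of 0.53 and its median was 0.49 at means of 10 to 100 and 0.30 at means of 1 to 2, so fold changes of low features may have been drawn toward 0, which was not tested. All 38 mitochondrial genome features and all 118 Y chromosome features had a mean of 0. Whether reads of these sequences were counted at all is not known, so the zeros were not taken as a lack of expression.

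The planned edgeR test, its normalization and filter alternatives and the replicate block need counts per library, which were not analysed here. The authors' DESeq2 values therefore stand as the test, with an adjusted p under 0.05. Feature identifiers were matched to the Ensembl annotation of BDGP6 in release 115, which held 23851 of them, for symbols, positions and gene types; all positions are 1-based in that annotation. Genes of ubiquitous complexes served to check the names along each arm. A name-checked stretch ran from an arm's left end to the last such gene with a mean of at least 100 before the first cytoplasmic ribosomal protein gene with a mean under 10000, and needed 3 ribosomal protein genes. This check was designed after the values were seen.

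The 38 gene lists, the comparison and the rule for named genes were fixed before the data were examined. The rule took, within the name-checked stretches, the 10 largest changes in each direction at an adjusted p under 0.05, the 5 most abundant features at least 2-fold apart in each direction, up to 4 members per list by smallest p with any needed to describe the count, byn, and the 3 largest folds of each deposited list. Its condition of at least 5 CPM was applied to the deposited mean, as a mean of at least 147, and its condition on single libraries could not be applied. Features used to describe the name check (Act5C, RpL32, fkh and alphaTub84B), aurB and Nha1 were chosen after their values were seen. So were genes named for a call gained or lost on recentring and the gene clusters in the closing section. Older symbols were matched through the reference's synonyms; RPA2 was left out because its synonym pointed to a ribosomal protein gene. In place of camera on a count fit, limma 3.58.1 in R 4.3.3 ran cameraPR on the deposited Wald scores of the name-checked stretches, two-sided, with a preset correlation of 0.01, over the 29 lists with at least 3 tested genes. Camera was tested on simulated data: with the Wald scores of the 2604 features shuffled, 2.80% of 500 random lists of 10 genes had a p under 0.05, and 91.2% did after 5 was added to their scores. Shuffling removes any correlation between genes, so the 2.80% does not apply to lists of co-regulated genes. For the 37 lists with a tested member, counts adjusted over the list alone equalled those over all features in 30. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 made the other values and the figures. The alternatives run were an adjusted p under 0.01, no low-mean filter and, chosen after seeing the data, protein-coding features only, a mean of at least 100, recentring on ribosomal protein genes, adjustment over the name-checked stretches alone, a Wald test against a fold of 2, camera on ranks, camera with a correlation of 0.05 and camera on all named features.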

Results

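RNA was sequenced from the hindgut of adult Drosophila melanogaster at 2 ages after emergence from the pupal case. The animals carried byn-Gal4, a driver line named for brachyenteron, the T-box transcription factor gene of the developing hindgut. All were reared at 25 °C. Young guts were taken as the adults emerged, and mature guts after the adults had been kept for 4 days at 18 °C. The labels give adult ileal cells as the cell type, the ileum being the long tubular part of the hindgut. Each condition comprised 100 to 150 guts and 3 replicates, so 6 libraries stood behind the comparison. Age and the temperature at which the adults were kept changed together and could not be separated. The values came from a single table, the authors' deposited table, with a mean over the libraries and an estimated fold change between the ages for each of 23932 features. Read depth per library was not analysed here; the means in the authors' deposited table summed to 2.94e+07 normalized counts. All fold changes were written for young against mature, so that a positive log2 value was higher in young guts.

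Genes that every cell needs were mostly listed at high means on only part of the genome, though some elsewhere were listed high too. In the authors' deposited table, 69 genes of ubiquitous complexes (ribosome, respiratory chain, proteasome, translation factors, chaperonin and tRNA synthetases) on chromosome arm 2L up to position 22247875 and on 3L up to position 5149852 had a median mean of 7524, with 1 gene below 10. The other 250 such genes had a median mean of 3.63 in the authors' deposited table, and 139 of them lay below 10. The 16 cytoplasmic ribosomal protein genes in the 2L stretch had a lowest mean of 28247, whereas the median of 17 on 2R and of 18 on 3R was 0 and that of 11 on X was 2.52 in the authors' deposited table. A stretch ended before the first such gene under 10000, so these contrasts were partly built in. Over the whole of 2L, 17 such genes had a median mean of 56220 and a lowest of 145, and 1 of 55 ubiquitous genes lay below 10. The actin gene Act5C on X was listed at a mean of 1.35 and the ribosomal protein gene RpL32 on 3R at 0 in the authors' deposited table. The transcription factor gene fkh on 3R, a regulator of gut development, and the tubulin gene alphaTub84B on 3R were also listed at 0 in the authors' deposited table. Accordingly, gene names are reported for those stretches of 2L and 3L, called the name-checked stretches, which held 5237 features and 41.1% of the summed mean. Counts for the whole table are given beside them.

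**Figure D1:**
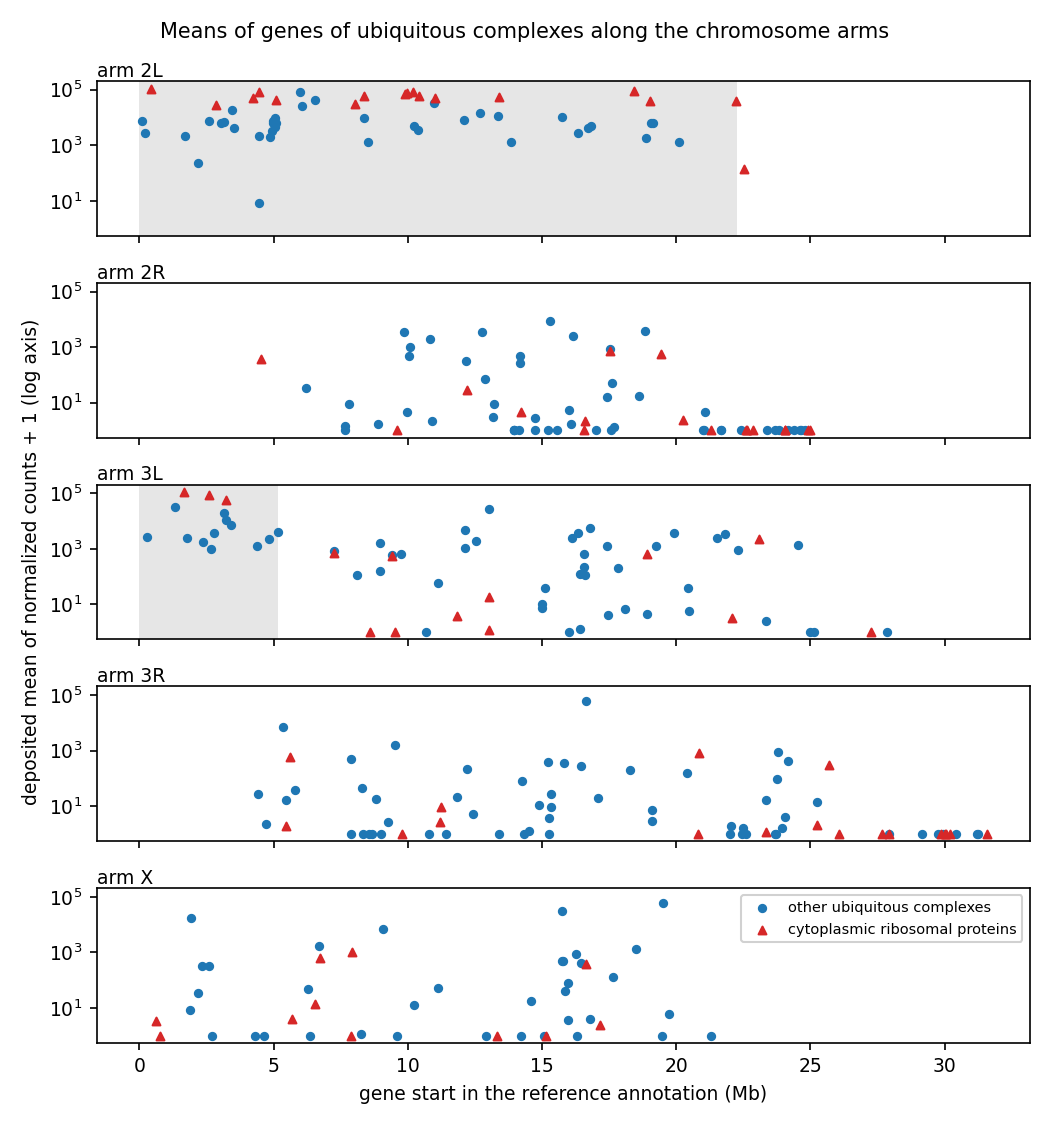
Deposited mean of normalized counts plus 1 (log axis) for genes of ubiquitous complexes against their start in the reference annotation (Mb), 1 panel per chromosome arm, with cytoplasmic ribosomal protein genes as red triangles, the other complexes as blue circles and the name-checked stretches shaded. In the shaded stretches 1 of 69 genes lay below a mean of 10, and elsewhere 139 of 250 did.

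Which genes differed between young and mature hindguts was the question of the comparison. In the name-checked stretches, 538 features were higher in young guts and 512 were higher in mature guts at an adjusted p under 0.05, out of 2604 tested, and the median absolute log2 change of these 1050 was 0.72 in the authors' deposited table. At least 2-fold, 203 were higher in young and 150 in mature, and at least 4-fold, 46 and 38. Genes of energy metabolism, the proton pump genes Vha68-2 and VhaSFD and both collagen IV genes were higher in young guts, while the matrix protein gene Tig, the Idgf genes and several lipid genes were higher in mature guts. Over the whole table, 1705 of 10458 tested features were higher in young and 1608 in mature, with 600 and 487 of them at least 2-fold apart. With all fold changes recentred on the ribosomal protein genes, whose median was 0.17 (log2), 412 features of the name-checked stretches were higher in young and 808 in mature, and 156 and 228 of them were at least 2-fold apart. Before recentring, the median log2 change was already -0.0070 over the tested features of those stretches and -0.0045 over the whole table. Recentring takes the ribosomal protein genes as unchanged, which was not tested, and adds no error for the shift. A Wald test against a 2-fold change, in place of a limit on the estimate, left 123 of the 353 features at least 2-fold apart.

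The largest change toward young guts in the name-checked stretches was that of CG32266 (3L, 3790804 to 3791560), 281-fold in the authors' deposited table (log2 8.13, standard error 0.31, adjusted p = 7.78e-152); it overlaps the more abundant gene CG32264. The pseudogene CR44079 and the trypsin-like protease gene Try29F followed at 16.3-fold and 14.1-fold in the authors' deposited table. NimC4, a phagocytic receptor for dying cells, was 13.4-fold higher in young and nolo, an extracellular ADAMTS-like protein, 13.2-fold in the authors' deposited table. The receptor for bursicon, the neurohormone of cuticle tanning, rk (2L, 13982743 to 14001248), was 12.7-fold higher in young guts in the authors' deposited table (log2 3.66, standard error 0.21, adjusted p = 7.07e-65). CG33003, twit, eys and CG13082 were 9.17-fold to 12.3-fold higher in young in the authors' deposited table, eys overlapping the more abundant CG9967. Among features at least 2-fold higher in young, the 5 with the highest means in the authors' deposited table were Vha68-2 (457096), VhaSFD (129771), mAcon1 (109888), nrv1 (93736) and Cyt-c-p (70504).

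The largest change toward mature guts in the name-checked stretches was that of CG7296 (2L, 10686124 to 10687066), 16.4-fold in the authors' deposited table (log2 -4.04, standard error 0.12, adjusted p = 1.93e-245). Tig (2L, 6415179 to 6423310), the integrin-binding matrix protein tiggrin, was 15.3-fold higher in mature guts in the authors' deposited table (log2 -3.93, standard error 0.11, adjusted p = 1.83e-299). CG17264 was 13.9-fold, CG13116 13.3-fold, CG7294 10.9-fold and Nlg2, a neuroligin, 10.3-fold higher in mature in the authors' deposited table. CG3604, Ttc30 (an intraflagellar transport protein), firl and CG31809 were 6.88-fold to 9.27-fold higher in mature in the authors' deposited table. The most abundant features at least 2-fold higher in mature were CG1143 (mean 170874, 2.27-fold), CG14949 (121132, 2.32-fold), CG16713 (86845, 5.80-fold), Tig (81083) and CG3604 (80718, 9.27-fold) in the authors' deposited table.

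**Figure D2:**
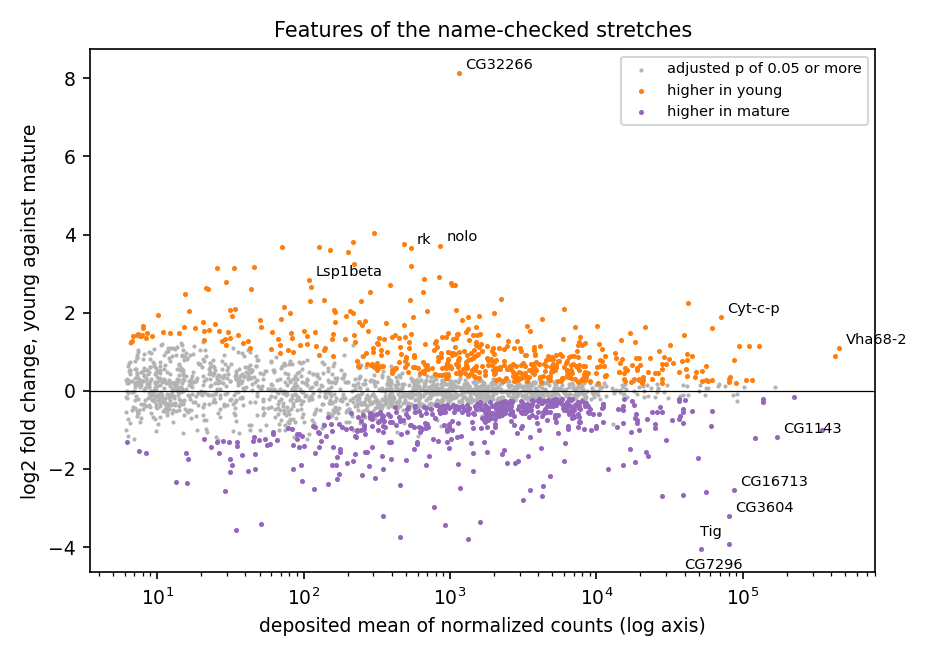
Log2 fold change, young against mature, against the deposited mean of normalized counts (log axis) for the 2604 tested features of the name-checked stretches, with features at an adjusted p under 0.05 in orange (538 higher in young) and purple (512 higher in mature) and the rest in grey. CG32266 stands alone at 8.13, and the abundant genes Tig, CG7296, CG3604 and CG16713 lie between -4.04 and -2.54.

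Nuclear genes of mitochondrial respiration were higher in young guts as a group. Of 17 oxidative phosphorylation genes tested in the name-checked stretches, 15 were higher in young, 1 was higher in mature and 1 did not pass, with the same counts adjusted over the list alone. Their median log2 change was 0.64, and limma's camera ranked the list above other genes (adjusted p = 3.72e-05). The electron carrier gene Cyt-c-p was 3.72-fold higher in young (log2 1.90, standard error 0.10, adjusted p = 2.36e-78) in the authors' deposited table. Complex I subunits ND-ACP, ND-15 and ND-B22 had log2 changes of 0.81, 0.87 and 0.76 in the authors' deposited table. The exception was COX7AL2, a low-abundance paralog of a cytochrome c oxidase subunit, which was 2.27-fold higher in mature in the authors' deposited table. The list of glycolysis and tricarboxylic acid cycle genes moved the same way, with 6 of 7 genes higher in young and none in mature, also when adjusted over the list alone (camera adjusted p = 0.000507). Among those higher in young, Pgk and Eno encode enzymes of glycolysis. Glyp encodes an enzyme that breaks down glycogen and fbp (log2 0.64) one of gluconeogenesis, so the list does not show a rise of glycolysis itself. In that list, mAcon1, the mitochondrial aconitase, was 2.21-fold higher in young in the authors' deposited table, and Scsalpha1, Glyp and Pgk had log2 changes of 0.76, 0.68 and 0.69. The muscle genes Mhc and sls, at log2 changes of 0.90 and 0.63 in the authors' deposited table, were higher in the same guts. The remaining muscle gene tested, Msp300, was higher in mature guts (log2 -0.21). Oxidative phosphorylation and glycolysis with the TCA cycle were the only lists of the 29 tested at a camera adjusted p under 0.05. With no low-mean filter 7 lists were, adding chitin, ion transport, lipid metabolism, V-ATPase and muscle. After recentring, cype and Eno lost their calls, which left 14 of 17 oxidative phosphorylation genes and 5 of 7 glycolysis and TCA cycle genes higher in young.

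Of 19 cytoplasmic ribosomal protein genes, 9 were higher in young and none in mature, or 10 adjusted over the list alone, with a median log2 change of 0.17 (camera adjusted p = 0.321). The changes were small, with RpL7 at 0.31, RpL23A at 0.27, RpL28 at 0.27 and RpS13 at 0.26 in the authors' deposited table. Recentring on these genes, which puts their median at 0 by construction and so cannot test their direction, left none higher in young and 4 higher in mature. Of 4 proteasome genes, among them Prosalpha6 (log2 -0.18, adjusted p = 0.0874) in the authors' deposited table, none passed, though 3 were higher in mature after recentring.

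Genes of ion transport included some of the most abundant transcripts. Of 7 vacuolar ATPase genes, which encode the proton pump, 3 were higher in young and none in mature, also when adjusted over the list alone (camera adjusted p = 0.117). Vha68-2 was 2.12-fold and VhaSFD 2.23-fold higher in young in the authors' deposited table (adjusted p = 2.50e-36 and 4.46e-40); Vha68-1, at a log2 change of 0.36, no longer passed after recentring, and VhaM9.7-c was then higher in mature. Of 12 ion and water transport genes, 4 were higher in young and 2 in mature, also when adjusted over the list alone (camera adjusted p = 0.117). The carbonic anhydrase gene CAH1 was 2.80-fold and the Na,K-ATPase beta subunit gene nrv1 2.20-fold higher in young in the authors' deposited table, nrv2 had a log2 change of 0.46, and the exchanger gene Nhe3 one of -0.43. The antiporter gene Nha1, with a mean of 165721, had a log2 change of 0.11 (adjusted p = 0.386) in the authors' deposited table.

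Muscle and matrix genes split. Of the 3 muscle genes tested, the myosin heavy chain gene Mhc (log2 0.90) and the titin-like sls (0.63) were higher in young and Msp300 (-0.21) was higher in mature in the authors' deposited table, with the same counts adjusted over the list alone (camera adjusted p = 0.103). The Msp300 call (adjusted p = 0.0396 in the authors' deposited table) was lost with no low-mean filter. Of 6 basement membrane and matrix genes, 5 were higher in young and Tig was higher in mature, also when adjusted over the list alone (camera adjusted p = 0.770). Pxn lost its call after recentring, which left 4 higher in young. The collagen IV genes vkg and Col4a1 were 2.53-fold and 2.34-fold higher in young in the authors' deposited table, and the laminin gene LanB1 had a log2 change of 0.84. The hemocyte markers NimC1 and Sr-CI, at means of 26.6 and 35.7, were 2.90-fold and 2.69-fold higher in young, and crq, at a mean of 8852, had a log2 change of -0.57 in the authors' deposited table (camera adjusted p = 0.757 for the hemocyte list).

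**Figure D3:**
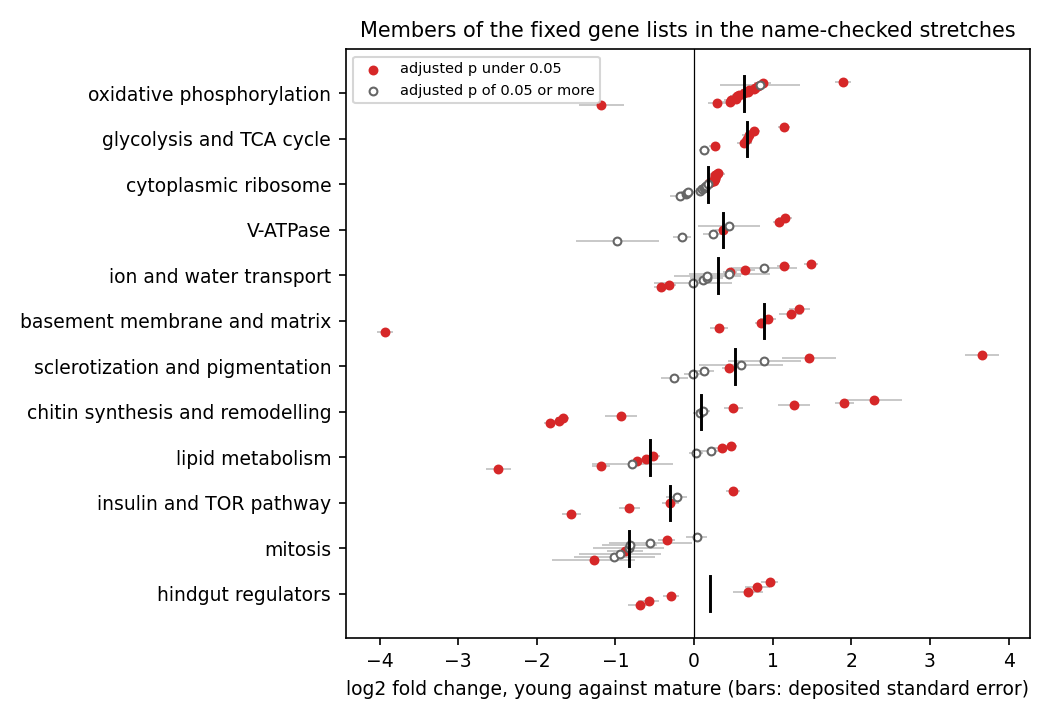
Log2 fold change, young against mature, of each tested member of 12 fixed gene lists in the name-checked stretches, with bars for the deposited standard error, filled points for an adjusted p under 0.05, open points for the rest and a vertical black line at each list's median. The medians of oxidative phosphorylation (0.64) and of glycolysis and the TCA cycle (0.68) lie to the right of 0, and that of lipid metabolism (-0.56) to the left.

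Genes of the cuticle and its chitin went both ways. Of 10 chitin genes, 4 were higher in young, 4 were higher in mature and 2 did not pass, also when adjusted over the list alone; the median log2 change was 0.09, the mean -0.00025, and camera pointed to mature (adjusted p = 0.117). Idgf1, Idgf2 and Idgf3, chitinase-like proteins without the enzyme activity, were 3.55-fold, 3.19-fold and 3.30-fold higher in mature in the authors' deposited table. The chitinase genes Cht2 and Cht7 were 3.76-fold and 4.90-fold higher in young in the authors' deposited table. Of 12 cuticle protein genes, Cpr62Bb (log2 1.11) and Vajk2 (1.78, overlapping the more abundant Ance-3) were higher in young, Cpr23B (-2.34, at a mean of 13.4) was higher in mature and 9 did not pass in the authors' deposited table, with the same counts adjusted over the list alone (camera adjusted p = 0.731). Of 8 sclerotization and pigmentation genes, rk, yellow-b (log2 0.45) and b (1.46) were higher in young in the authors' deposited table and none in mature, also when adjusted over the list alone (camera adjusted p = 0.141), though yellow-c was higher in mature after recentring. The ecdysone pathway list held 1 gene higher in young, ImpL2 (3.53-fold in the authors' deposited table), an insulin antagonist, and 4 of 7 higher in mature, among them Hr38 (log2 -1.05), also when adjusted over the list alone (camera adjusted p = 0.983).

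Among lipid and nutrient-signalling genes that passed, more were higher in mature than in young guts. Of 10 lipid metabolism genes, 5 were higher in mature and 2 in young, also when adjusted over the list alone (camera adjusted p = 0.103, or 0.0366 after recentring). CPT2 lost its call after recentring, which left 5 higher in mature and 1 in young. The lipase gene Lip4 was 5.63-fold higher in mature, the sterol-binding Npc2a 2.28-fold, Npc1a had a log2 change of -0.73 and the nuclear receptor Hnf4 one of -0.61 in the authors' deposited table. Of 5 insulin and TOR pathway genes, 3 were higher in mature and 1 in young, also when adjusted over the list alone (camera adjusted p = 0.281). REPTOR-BP, the partner of a TORC1-repressed transcription factor, was 2.96-fold and the translation repressor gene Thor 1.77-fold higher in mature in the authors' deposited table.

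Hindgut patterning genes and cell division genes were also examined. All 6 tested hindgut regulators differed, 3 in each direction and also when adjusted over the list alone (camera adjusted p = 0.757). The zinc finger gene drm (log2 0.96), the homeobox gene cad (0.81) and the ligand gene wg (0.69) were higher in young, and dpp (-0.69), raw (-0.58) and bowl (-0.29) were higher in mature in the authors' deposited table. Of 9 mitosis genes, barr (log2 -0.88), Top2 (-0.35) and borr (-1.28, adjusted p = 0.0499) were higher in mature in the authors' deposited table and none in young, or 4 adjusted over the list alone (camera adjusted p = 0.492). The borr call was lost with no low-mean filter. The driver gene byn (3L, 11927693 to 11935919), outside the name-checked stretches, was listed at a mean of 100.4 with a log2 change of 0.71 (standard error 0.35, adjusted p = 0.116) in the authors' deposited table.

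The authors also listed 132 features as young and 91 as mature. All 132 and 90 of the 91 passed an adjusted p of 0.05 in the listed direction; the other, aurB, had a log2 change of -2.47 without a p in the authors' deposited table. The smallest absolute log2 changes listed were 1.96 and 1.97 in the authors' deposited table, and the lists are a selection from the same comparison, so they are not independent evidence. Of these features, 49 and 40 lay in the name-checked stretches. The 3 largest folds of the young list were those of CG32266, 5SrRNA:CR33353 (2R, log2 5.95) and Gr89a (3R, 5.37), and those of the mature list were CG16700 (X, -6.49), lncRNA:CR44950 (3R, -4.84) and CG7296 in the authors' deposited table; of the 6, CG32266 and CG7296 lay in the name-checked stretches.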

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

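No paired analysis was possible because the deposited columns hold no value per library. For the same reason RLE and upper quartile scaling, the edgeR, robust, voom and separate DESeq2 fits, the CPM filter, leaving out each library, glmTreat, camera with an estimated correlation and fry were not run, splits of the libraries could not be counted, and the stability of any call to a single library is unknown. An adjusted p under 0.01 and no low-mean filter were planned; all other alternatives were chosen after seeing the data. The counts of changed features, and those at least 2-fold apart, stayed within 1.5 times under all of them but 1: a Wald test against a fold of 2 left 305 of 1087 features in the whole table and 123 of 353 in the name-checked stretches, as its stricter null implies. Recentring moved the split in the whole table from 1705 and 1608 to 1191 higher in young and 2644 higher in mature, and at least 2-fold apart from 600 and 487 to 416 and 719. With no low-mean filter 7 gene lists in place of 2 had a camera adjusted p under 0.05. Chitin, ion transport, lipid metabolism and muscle held the same 10, 12, 10 and 3 genes in both settings. Their own Wald scores were unchanged, so their lower p-values came from the features they were compared with. V-ATPase held 8 genes in place of 7. Oxidative phosphorylation and glycolysis with the TCA cycle passed under every camera setting run. The setting on all named features took in arms where the names did not hold, so passing there adds no support. In that setting the muscle list passed too (19 genes, camera adjusted p = 0.0150). Of 152 gene names followed, none changed direction past the threshold; 11 lost their call at 0.01, 2 with no low-mean filter and 8 after recentring, when 8 others gained one. All 222 features of the deposited lists that passed at 0.05 also passed at 0.01.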

Other observations

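The test of a lack of transcription, the offset tests by arm, 2 of the 3 offset scans, the genes named for recentring, the comparison of transposable elements matched on the mean and the neighbouring genes named at the end were chosen only after their values were seen. In the name-checked stretches, fat body genes were 3 higher in young and 3 in mature: the larval storage protein genes Lsp1beta (7.15-fold, mean 109.1) and Lsp1gamma (3.56-fold, mean 69.8) were higher in young, and Apoltp (log2 -0.75) and Tps1 (-0.60) were higher in mature in the authors' deposited table. Hemocyte genes were 3 of 6 higher in young, namely Col4a1, which the matrix list also holds, and the low-abundance NimC1 (mean 26.6) and Sr-CI (mean 35.7), and 1 higher in mature, crq (log2 -0.57), in the authors' deposited table. Of 7 midgut genes, nub (2.31-fold) and LManII (1.76-fold) were higher in young and Jon25Bi (log2 -1.58, mean 26.5) was higher in mature in the authors' deposited table. Of 4 neuronal genes nSyb (3.75-fold) and Rbp9 were higher in mature, and of 2 tracheal genes both uif (log2 0.66) and trh (0.58) were higher in young in the authors' deposited table. None of 3 Malpighian tubule, 2 male and 5 female reproductive tract genes passed. For neurons, the list's median was 0.04, its mean -0.21, and camera pointed to mature.

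Among enzymes and signalling genes, 5 of 13 cytochrome P450 genes were higher in young and Cyp4ac3 was 3.05-fold higher in mature in the authors' deposited table, although its neighbour Cyp4ac1 was 4.07-fold higher in young; both overlap the more abundant tkv. The 9 genes tested from the list of glucuronosyl and glutathione transferases were all Ugt genes, of glucuronosyl transferases, and no glutathione transferase gene was tested. Of these 9, 4 were higher in young and none in mature, led by Ugt37C2 (5.74-fold in the authors' deposited table). Tep4 and Tep2, thioester immune proteins, were 1.87-fold and 1.86-fold higher in mature, and the oxidase gene Duox was 2.68-fold higher in young in the authors' deposited table. The other 4 immune genes tested did not pass; the list's median was 0.29, its mean 0.02, and camera pointed to mature. Junction genes were 2 of 9 higher in young, vari (log2 0.85) and hoka (1.09), and 4 higher in mature, led by Fas3 (-0.86) and Mcr (-0.61), in the authors' deposited table. The cadherin gene ft was 3.71-fold and ds 1.45-fold higher in young, and ex, which overlaps crq, 1.44-fold higher in mature in the authors' deposited table. In the Notch list Su(H) was 2.48-fold higher in mature and kuz (log2 0.40) was higher in young in the authors' deposited table. Both JAK-STAT genes, Ptp61F (log2 -0.48) and Socs36E (-0.24), 2 of 3 autophagy genes, Atg18b (-0.57) and Atg2 (-0.25), and the cell death gene grnd (-0.23) were higher in mature in the authors' deposited table. Of 12 DNA replication genes Ts (2.28-fold), which overlaps Rbp9, was higher in young and Psf1 (1.59-fold) in mature in the authors' deposited table. Hsp83, the clock genes tim and vri, and msl-2 did not pass, and no Osiris gene was tested. Adjusted over the list alone, 6 cytochrome P450 genes and 3 junction genes were higher in young, 3 autophagy genes were higher in mature, 1 Malpighian tubule gene was higher at each age and 1 neuronal gene was higher in young. After recentring, kuz, trh, Ugt36D1 and Fbp2 no longer passed, and Atg4a, cold, vri, ush, Uro and vas were higher in mature. None of these lists with at least 3 tested genes had a camera adjusted p under 0.05.

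Ubiquitous genes had a mean below 10 in 48 of 69 cases on 2R, 49 of 77 on 3R, 23 of 47 on X and 19 of 67 on 3L, but 47.5% of the 3334 features with a mean of 1000 or more lay on 2R, 3R and X, which argues against low depth. A candidate explanation is that reads were placed on one genome release and counted with the gene positions of another. For this, 1 offset per arm was estimated from ribosomal protein genes (4112350 bases on 2R, 4174500 on 3R and 105950 on X). At these offsets, genes of the respiratory chain, proteasome and proton pump fell on features with means per kb of 900, 1066 and 1447. These means per kb were averaged as log2 values and turned back. With the chosen offset counted among 1000 random ones, at most a share of 0.0020 gave as high a value. All shares here were counted in that way. Under the other 2 scans the share stayed at or under 0.0040 on 2R and 3R, which argues against genes there being little transcribed, whereas X, at a share of 0.00100 in the first, moved to offsets of 1424850 and 1417650 with means per kb of 1.09 and 5.20 and shares of 0.970 and 0.732. On 3L an offset of 7300 had a share of 0.169. That scan applied 1 offset to the whole arm, including the stretch where names held as listed, so it cannot decide for the rest of 3L. On 2L, where names held, the first scan chose -2567800 (4.11 per kb, share 0.974) and the others 0 with a share of 0.074. The test can thus miss a right offset, and a change of release stays open for X and 3L. The 11 cytoplasmic ribosomal protein genes on X had a median mean of 2.52, with 7 below 10, and on 3L 6 of 14 lay below 10. The 17 on 2L, which encode parts of the same ribosome, had a median mean of 56220. This contrast argues against low transcription for those ribosomal protein genes. For the other genes of X and 3L low transcription stays open. The features under the shifted positions of 18 respiratory chain genes on 2R, 3R and X had a median log2 change of 0.48, above the 0.23 that 95% of random offsets stayed under, and 12 on 2R and 3R alone had 0.42 against 0.30, so fold changes listed on 2R and 3R may belong to genes an offset away.

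Transposable element features held 7.12% of the summed mean in the authors' deposited table and are part of the counts of the report: 370 of 1735 tested passed an adjusted p of 0.05 in the whole table, and in the name-checked stretches 28 were higher in young and 23 in mature. The share was 0.572% of the summed mean in the name-checked stretches and 11.03% on 2R, 3R, X and the rest of 3L, a ratio of 19.3. A candidate explanation is that features on arms where the names did not hold collected reads of other genes, and the ratio of 19.3 goes with it, since it needed at least 3. The ratio was not corrected for the number of such features, so it does not decide the question. They were 215 of 2604 tested features in the name-checked stretches and 1735 of 10458 in the whole table. Whether transcription of transposable elements itself differed with age cannot be told apart from low abundance: in the name-checked stretches 23.7% of 215 such features passed, against 41.8% of the others (Fisher's exact p = 1.34e-07) but 27.4% of others matched on the mean (Fisher's exact p = 0.439). The matched comparison was added because the median mean was 69.1 for transposable element features and 816 for the others.

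Neighbouring genes of the name-checked stretches had similar fold changes, across genes, which are not independent replicates. On 2L, CG7296, CG7294 and CG17108 were 16.4-fold, 10.9-fold and 6.37-fold higher in mature between positions 10686124 and 10694103, and CG16704, CG16713, IM33 and CG3604, genes of Kunitz-type proteins, were 6.44-fold, 5.80-fold, 1.99-fold and 9.27-fold higher in mature between 3692123 and 3697872 in the authors' deposited table. Pearson's r of the log2 changes was 0.133 over 895 pairs at least 1 kb apart, above the 0.109 reached in 1000 shuffles, which argues against reads shared between overlapping genes as the whole cause. Without pairs that share a symbol stem or a list r was 0.031 over 739 pairs. The stem was cut at the first digit, so neighbouring genes named only by CG numbers always counted as sharing it. The fall in r therefore cannot tell tandem copies of gene families from unrelated neighbours. The r of the 299 nearest pairs, at most 3126 bases apart, exceeded that of the 299 farthest by 0.32 (95% interval 0.12 to 0.51). Co-regulation of neighbours with age predicts such a difference. Tandem copies and co-regulation both stay open.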
